A study of Synechocystis sp. PCC 6803 with 12 samples.

How the data were processed

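The series measured RNA of the cyanobacterium Synechocystis on 12 one-colour arrays, with 2 arrays for each of 6 groups made by 2 genotypes (wild type and a ΔkaiAB1C1 mutant) and 3 times. Per the labels, cultures grew at 30 °C under 50 µmol photons per m2 and s, were held in constant light for 3 days and then moved to cycles of 12 h light and 12 h dark. They were sampled at CT17.5 and CT5.5 of the first period and at CT5.5 after 6 days. Per the labels, RNA was treated with DNase and labelled directly with Cy3 without synthesis of cDNA. The labels do not say whether the 2 samples of a group came from separate cultures. They also do not say from which event CT was counted.

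The deposited scanner files hold intensity values made with Feature Extraction 10.7.3.1, per the file headers. The processed signal of each spot is its brightness after background subtraction and detrending within the array, and low spots hold a substitute value. The deposited mean, median and local background signals are scanner intensity with no correction, per the file headers. Other columns, per the file headers, are marks of 0 or 1 that say whether a spot was well above background, saturated or uneven. The deposited series table holds log2 values that equal, spot by spot, the log2 of the median signal after quantile normalization over the 12 arrays, with no background subtraction. The authors name limma, without a version, among their tools. No array pooled samples, and there was 1 channel, so no value had a second sample as its reference.

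Each array held 42303 spots, of which 1417 were controls and 40886 were used. Spots marked as outliers were left out, the log2 processed signal of each spot was lowered by the array's 75th percentile, and spots were averaged to 20363 probes and probes to 8830 features. Of the probes, 20343 had 2 spots and 20 had 10 spots. A feature was kept if 1 of its probes was well above background on both arrays of at least 1 group, which kept 7991 features: 3265 of 3356 protein genes, 1460 of 1928 antisense features, 1766 of 1875 features named int, 669 of 710 5' untranslated features, 511 of 600 noncoding RNAs, 40 of 40 tRNAs, 3 of 3 rRNAs and 277 of 318 others. Depth on an array is the signal over background: 3010 features and 7480 spots were well above background on all 12 arrays. The number of arrays limits the precision of every value, and p-values measure only the spread between these samples.

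A model with 1 mean per group was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (with the package data.table, version 1.17.8, to read files), which left 6 residual degrees of freedom and used limma's moderated test. A coefficient was missing for 13 features because of spots left out. The 11 contrasts were the genotype difference at each time, its mean over the 3 times, the 3 differences of genotype differences between times, and the changes from CT5.5 of the first period to the other times in each genotype. P-values were adjusted by the method of Benjamini and Hochberg over the 7991 features of a contrast, and a feature was called at an adjusted p under 0.05. All tests were two-sided. Errors given as ± are standard errors from this model.

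Dim spots have no reliable value, so a group counts as having measured a feature if at least 1 of its arrays was well above background. Where only 1 of the groups compared measured a feature, its difference is given as a bound, except in differences between times, which have none and are marked where a group did not measure the feature. The bound sets the mean of the group that measured it against the other group with each array raised to the dimmest spot still well above background on that array, and no fold is given where this leaves no difference or reverses it. A call is described as holding in every scaling if the feature was measured in both groups, or held by its bound, and was called in the same direction with 5 other scalings. These were normexp background correction with an offset of 50, quantile normalization, each array's median, the 75th percentile of the 7480 spots well above background on all 12 arrays, and the deposited series table. Each of them, like the main scaling, sets the arrays to a common level. Every rise or fall is thus relative to the level of its array, and no scaling tests a change of that level. Where the median difference of measured protein genes was over 0.1 on the log2 scale, single genes are described relative to that median, and list medians are relative to it in every contrast, while tests and standard errors are those of the fitted values.

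Before the data were examined, 25 lists with 305 genes were fixed, along with the comparisons, the tests, the rule for naming genes and all alternatives except 4. The lists were the deleted kai cluster, other kai and clock output genes, sigma factors, photosystem I, photosystem II, cytochrome b6f and soluble carriers, phycobilisome, ATP synthase, inorganic carbon uptake, carboxysome and Rubisco, Calvin cycle, glycogen and sugar breakdown, NDH-1 core, terminal oxidases, bidirectional hydrogenase, ribosomal proteins, chaperones and proteases, high light and oxidative stress, iron homeostasis, nitrogen assimilation, phosphate uptake, pili, motility and cAMP, the phototaxis pix operon, tetrapyrrole and chlorophyll synthesis, and cell division and replication. The filter dropped 2 of these genes. Lists were tested with camera of limma against all other protein genes with a preset correlation of 0.01, and again with an estimated correlation, and adjusted over the 25 lists of a contrast. The median of a list is over its genes measured in every group compared. The rule named the deleted genes, then the 10 largest and 10 smallest changes of protein genes that were called and did not overlap between genotypes, the 3 largest and 3 smallest of other features, and up to 4 called members of each list. It took 5 in each direction for differences between times and 8 in each direction for changes with time. Its part on neighbours of the deleted cluster was not applied, since no table gave positions.

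Of the 3356 locus tags of protein genes, 0 appeared in the reference table, so symbols came from the fixed lists. The fit was tested on simulated data with 7924 features of which 200 were changed: a 2-fold change was recovered in 49% at CT17.5, 39% at the first CT5.5 and 53% at day 6, and a 4-fold change in 90%, 94% and 92%. It called 143, 144 and 156 features there, of which 4, 11 and 11 were false. The simulation had independent noise, no dim mutant arrays and no error of scaling. Its false calls therefore do not carry over to CT17.5 and day 6, where 55.1% and 63.2% of features were called. The list test was tested on a simulated list of 20 among 3265 genes, which it called when shifted by a log2 value of 1, while it called 0 of 24 lists that were not shifted. The simulated genes varied independently, so this cannot show how often lists of genes that vary together are falsely called.

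The alternatives fixed beforehand were the other background correction, quantile normalization, each array's median, the series table, no filter, a stricter filter, protein genes only, the median over probes, a 2-fold threshold, array weights, a prior with trend and robust fitting, only the arrays of the times compared, a block for the replicate number, leaving out each array in turn, and for lists fry, an estimated correlation and a block. Those chosen after seeing the data were the 75th percentile of spots above background on all 12 arrays, counts of measured or bounded calls, a crossed replicate block at day 6, and list tests on measured genes only. A hybridisation of genomic DNA that the labels mention was not analysed here.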

Results

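Transcripts of the unicellular cyanobacterium Synechocystis were measured on 12 arrays with probes for protein genes, antisense RNAs, 5' untranslated regions, noncoding RNAs and features named int. Wild type was compared with a ΔkaiAB1C1 mutant, deleted for the genes of the clock proteins KaiA, KaiB1 and KaiC1, at 3 times with 2 arrays per genotype and time. Cultures came from constant light and were sampled at CT5.5 and CT17.5 of the first light-dark period and at CT5.5 after 6 days. CT17.5 falls in the dark phase only if CT was counted from lights on, which the labels do not state. The 75th percentile of the processed signal, in scanner intensity units, was 3223 and 2427 in wild type and 3177 and 2172 in the mutant at the first CT5.5. At CT17.5 it was 645 and 749 in wild type and 439.7 and 489 in the mutant, and at day 6 it was 3028 and 2981 in wild type but 639 and 566 in the mutant. The mutant to wild type ratio of this percentile was 0.939, 0.667 and 0.200 at the first CT5.5, at CT17.5 and at day 6. Spots well above background made up 88.9% and 83.0% of wild type and 83.8% and 63.5% of mutant arrays at the first CT5.5, 37.8% and 41.4% against 28.6% and 29.0% at CT17.5, and 69.2% and 67.9% against 36.3% and 27.2% at day 6. Correlations between the 2 arrays of a group across features lay between 0.968 and 0.995. The highest was that of the mutant arrays of CT17.5, where many dim features held the same substitute value. How far this raised the correlation was not tested. Each time had its own slide of 4 arrays, so a change with time and a difference between slides cannot be told apart, whereas genotypes were compared within a slide. Wild type took array positions 1 and 2 and the mutant positions 3 and 4 on every slide, so position and genotype cannot be told apart either.

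**Figure D1:**
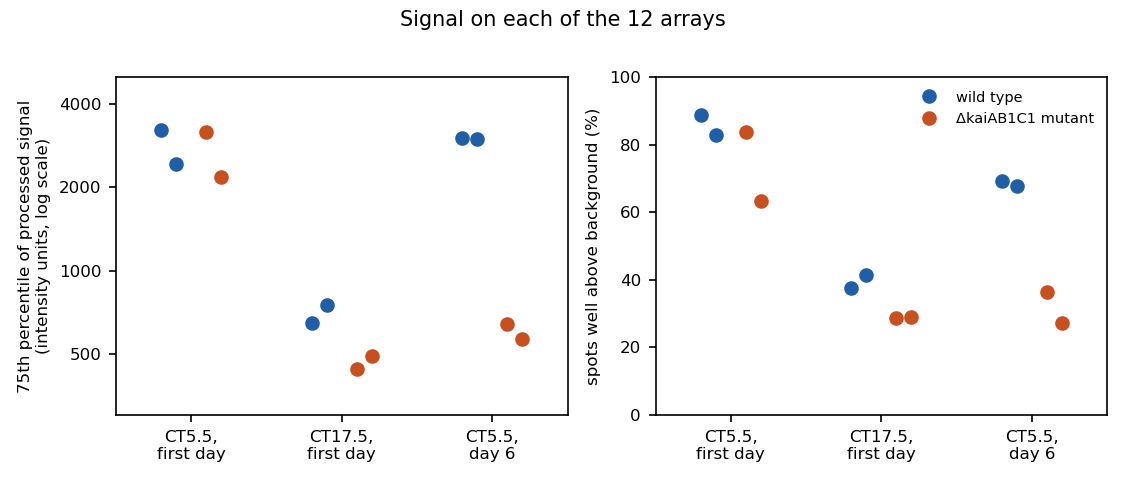
The 75th percentile of processed signal (intensity units, log scale) and the percent of spots well above background are plotted for each of the 12 arrays, with wild type in blue and the ΔkaiAB1C1 mutant in orange. The mutant arrays of day 6 stood at 639 and 566 intensity units beside wild type arrays at 3028 and 2981.

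The deleted genes were examined first. At the first CT5.5, kaiC1 (slr0758) was lower in the mutant by a log2 value of -1.65 ± 0.34 (limma, adjusted p = 0.017) and kaiB1 (slr0757) by -1.30 ± 0.33 (adjusted p = 0.044), each measured on 1 of the 2 mutant arrays. The difference of kaiA (slr0756) was -0.97 ± 0.36 and did not pass (adjusted p = 0.14). With quantile normalization the differences of kaiC1 and kaiB1 were -0.63 and -0.52 and did not pass either (adjusted p = 0.091 and 0.26). Of the 4 probes of the slr0756 feature, 1 was well above background on both mutant arrays at this time, at a mean log2 value of -1.72 beside -4.20 in wild type. The other 3 were above background on 0 mutant arrays, at -5.40, -5.18 and -3.99 beside -2.71, -2.92 and -2.61. For kaiB1 and kaiC1, 1 of 4 probes each was above background on 1 mutant array. Other features named after the cluster went both ways at this time. On both mutant arrays and higher were a probe of kaiA-1-x, at -0.51 beside -2.08 in wild type, slr0756-5'UTR at -0.99 beside -2.56 and kaiA-as2-0-x at -1.51 beside -3.30. By contrast, slr0758-int1 had 1 of 2 probes on 1 mutant array, at -4.30 beside -0.14, and no mutant array measured KaiBC-as1-0-x, KaiBC-as2-0-x, slr0756-int1 or kaiA-as1-0-x. At day 6 both wild type arrays measured slr0756, slr0757 and slr0758 and no mutant array did, and the dim mutant arrays left no bound. The same probe of kaiA-1-x was on 1 mutant array there, at -0.78 beside -1.08, and kaiA-as1-0-x was on both, at 3.92 beside -0.060. At CT17.5 kaiB1 was measured on 1 wild type array, and neither genotype measured kaiA or kaiC1. Both mutant arrays measured kaiA-as1-0-x there, at 1.32 beside 1.53 in wild type, while KaiBC-as1-0-x was on both wild type arrays but on no mutant array. Whether each probe lies inside the deleted segment is not known, since the labels do not give its ends.

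At CT5.5 of the first period, the comparison asked which transcripts differ without the kaiAB1C1 cluster soon after the shift from constant light. Nitrogen uptake genes rose: amt1, for an ammonium transporter, by 1.84 ± 0.19 on the log2 scale (n = 2 arrays per group throughout), nrtD by 1.72 ± 0.17, nrtB by 1.66 ± 0.20 and nrtC by 1.56 ± 0.22, the last 3 for subunits of the nitrate transporter. The gene of sigma factor SigE, sigE, known as an activator of sugar breakdown genes, fell by 4.50 ± 0.27 and was measured on 1 of 2 mutant arrays. With it fell, at the log2 differences given, gap1 of glycolysis at -2.43 ± 0.23, gnd of the oxidative pentose phosphate pathway at -1.68 ± 0.20, glgX1, for a glycogen debranching enzyme, at -1.48 ± 0.21 and pyk1, for pyruvate kinase, at -1.48 ± 0.23. Genes of the cytochrome c oxidase, which respires in the dark, fell too: ctaCI at -2.15 ± 0.17, ctaDI at -1.19 ± 0.20 and ctaEI at -1.06 ± 0.22. Outside the fixed lists, slr1594 and slr1152 rose by 3.39 ± 0.22 and 3.14 ± 0.32. By contrast, ssr2062 fell by 4.76 ± 0.51, as did sll0450 at -3.44 ± 0.24, slr1363 at -3.26 ± 0.28 and sll7067 at -3.08 ± 0.22.

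Among lists at the first CT5.5, nitrogen assimilation had 5 of 16 genes higher in every scaling and 11 that did not pass so, 8 higher when adjusted over the list alone, and a median of 0.73 above the median measured protein gene (camera, adjusted p = 5.6e-07). List medians here and below are relative to that gene and over genes measured in every group compared. Single genes at the first CT5.5 and day 6 are not, since the median gene moved by only -0.092 and 0.072 there in the main scaling. In the other scalings it moved by -0.28 to 0.063 at the first CT5.5 and by -0.62 to 0.28 at day 6, so single values depend on the scaling by as much. Nitrogen assimilation was the list that held at the first CT5.5 with an estimated correlation (adjusted p = 0.024). In glycogen and sugar breakdown 6 of 17 genes fell in every scaling and 0 rose, and 8 fell adjusted over the list alone. The median was -0.50 (adjusted p = 2.4e-06; adjusted p = 0.22 with an estimated correlation). Of the ribosomal proteins 0 of 26 genes passed in every scaling or adjusted over the list alone, with a median of 0.59 (adjusted p = 5.9e-06; adjusted p = 0.54 with an estimated correlation). In the other lists called higher 0 genes passed in every scaling. These were ATP synthase (median 0.82, 7 higher adjusted over the list alone, adjusted p = 4.7e-04), high light and oxidative stress (0.47, 1 higher, 4.7e-04), iron homeostasis (0.74, 7 higher, 8.4e-04), phototaxis (0.56, 2 higher, 0.015), carboxysome and Rubisco (0.35, 0 higher, 0.016), inorganic carbon uptake (0.60, 5 higher and 2 lower, 0.019) and pili, motility and cAMP (0.32, 0 higher, 0.032). With an estimated correlation their adjusted p-values were 0.46, 0.39, 0.19, 0.22, 0.54, 0.49 and 0.39 in that order, so these calls were lost. Photosystem II, with 0 of 26 genes past the test and a median of 0.33, was called higher (adjusted p = 0.010; adjusted p = 0.54 with an estimated correlation), but its direction turned to lower with quantile normalization (adjusted p = 0.96) and with the series table (adjusted p = 0.81). Called lower was the bidirectional hydrogenase, with a median of -0.44 and 3 of 5 genes lower adjusted over the list alone (adjusted p = 0.021; adjusted p = 0.39 with an estimated correlation). The deleted kai cluster was called lower as well, with 3 of 3 genes lower adjusted over the list alone and a median of -1.21 (adjusted p = 0.015; adjusted p = 0.39 with an estimated correlation). The 12 lists that were not called were sigma factors (adjusted p = 0.092), cytochrome b6f and soluble carriers (0.092), terminal oxidases (0.094), cell division and replication (0.17), photosystem I (0.17), phycobilisome (0.17), tetrapyrrole and chlorophyll synthesis (0.28), other kai and clock output genes (0.33), NDH-1 core (0.58), phosphate uptake (0.62), Calvin cycle (0.62) and chaperones and proteases (0.99). Quantile normalization ended the calls of ATP synthase (adjusted p = 0.05), phototaxis (0.059), the deleted kai cluster (0.067), inorganic carbon uptake (0.21), carboxysome and Rubisco (0.32) and pili (0.35).

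Over all features at the first CT5.5, limma called 99 higher and 310 lower in the mutant, and 39 and 140 held in every scaling, among them 19 and 42 protein genes. The split was 114 to 203 with quantile normalization, 248 to 284 with normexp, 152 to 221 with each array's median, 166 to 228 with the series table and 60 to 474 with the percentile of spots above background on all arrays. Without replicate 1 of the mutant 217 features were called, and without its replicate 2, 220. Among other features, Spacer17-2-x, Spacer27-2-x and Spacer21-2-x, whose names count spacers within sets 0, 1 and 2, were at least 73.4-fold, 72.5-fold and 69.99-fold lower.

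**Figure D2:**
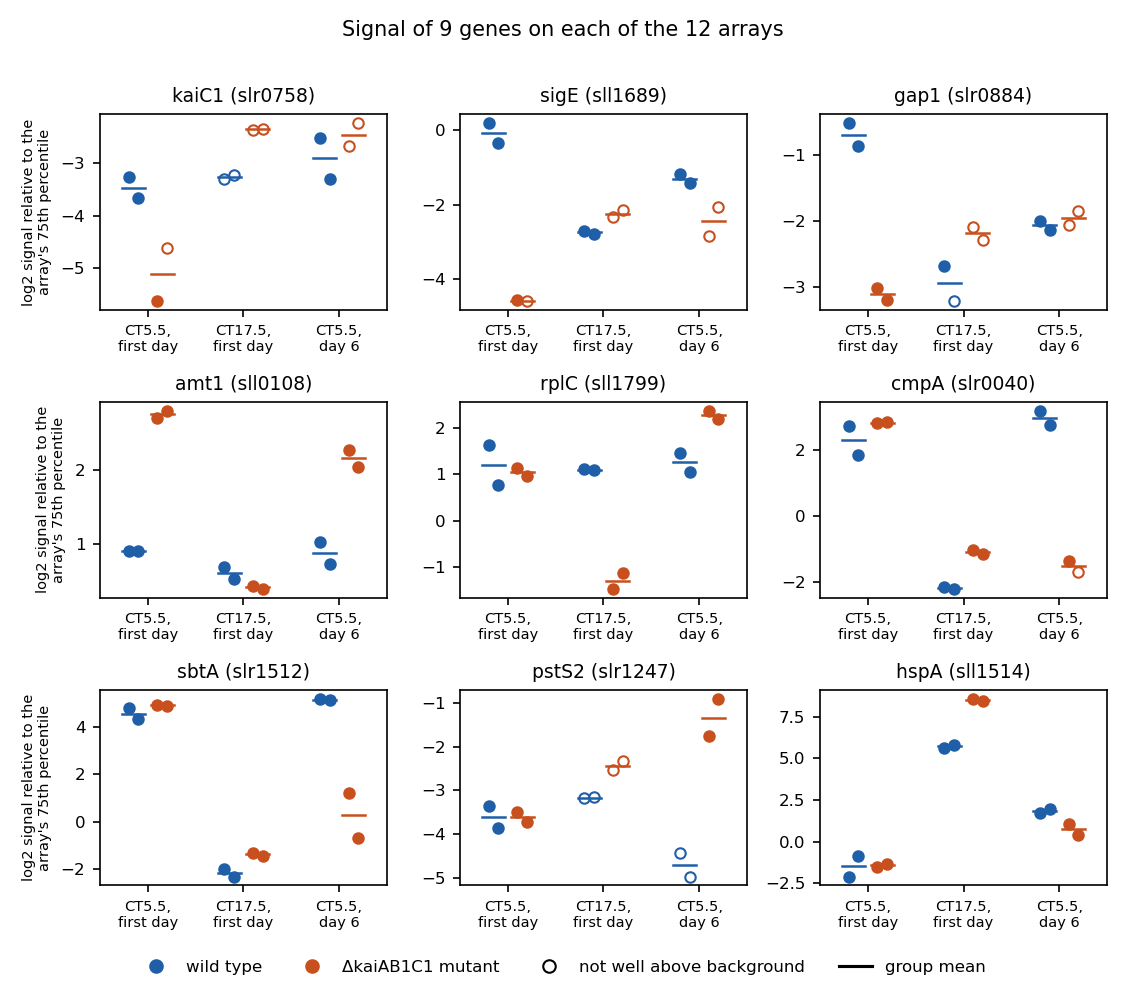
The log2 signal relative to the array's 75th percentile is plotted for kaiC1, sigE, gap1, amt1, rplC, cmpA, sbtA, pstS2 and hspA on each of the 12 arrays, with wild type in blue, the mutant in orange, bars for group means and open symbols where the gene was not well above background. At the first CT5.5 amt1 was higher in the mutant by 1.84 and gap1 differed by -2.43.

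At CT17.5 of the first period the same question was asked. The median measured protein gene was 0.48 higher in the mutant on the log2 scale, and the values here are relative to it. Ribosomal protein genes fell together, rplC at -2.89 ± 0.27, rplX at -2.84 ± 0.25, rplB at -2.80 ± 0.26 on 1 mutant array and rplD at -2.29 ± 0.20. Pilin genes fell, pilA1, for the main pilin of type IV pili, at -2.33 ± 0.18 and pilA11 at -2.32 ± 0.26. So did chlL of light-independent chlorophyll synthesis at -2.86 ± 0.35 and ocp, for the orange carotenoid protein, at -2.03 ± 0.24. The photosystem II gene psbF fell by 1.94 ± 0.22. Genes petB and petD of the cytochrome b6f complex fell, at -1.57 ± 0.24 and -1.53 ± 0.21. The heat shock and chaperone genes hspA, clpB1 and dnaK2 rose by 2.30 ± 0.34, 1.96 ± 0.19 and 1.63 ± 0.25. Also higher were cp12, for a regulator of the Calvin cycle, by 1.61 ± 0.18, psaB of photosystem I by 1.41 ± 0.22 and isiA, for an iron stress chlorophyll protein, by 1.40 ± 0.28.

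Of the ribosomal proteins 20 of 26 genes were lower in every scaling at CT17.5, 0 were higher and 6 did not pass so, while 25 were lower adjusted over the list alone. The median of 25 measured genes was -2.15 (camera, adjusted p = 4.5e-26; adjusted p = 0.45 with an estimated correlation). Most of the 26 genes have locus tags in the run from sll1799 to sll1822, and sll1096, sll1097 and sll1101 form another. The list may therefore stand for few gene clusters and not for ribosomal proteins at large. Its counts, here and in other contrasts, are not counts of independent genes. Pili, motility and cAMP had 8 of 17 genes lower and 0 higher in every scaling, 8 lower and 1 higher adjusted over the list alone, and a median of -1.28 over 14 measured genes (adjusted p = 5.1e-05; adjusted p = 0.29 with an estimated correlation). In photosystem II 7 of 26 genes were lower and 0 higher in every scaling, while 10 were lower and 6 higher adjusted over the list alone. The median of 23 measured genes was -0.69 (adjusted p = 6.4e-05; adjusted p = 0.58 with an estimated correlation). For cytochrome b6f and soluble carriers the counts were 5 of 13 lower in every scaling, 7 lower and 2 higher adjusted over the list alone. The median of 11 measured genes was -1.12 (adjusted p = 2.9e-04; adjusted p = 0.45 with an estimated correlation). High light and oxidative stress, with 3 of 16 genes lower in every scaling, 5 lower and 2 higher adjusted over the list alone and a median of -0.60 over 10 measured genes (adjusted p = 0.044), and carboxysome and Rubisco, with 0 of 11 in every scaling, 1 higher adjusted over the list alone and a median of -0.89 (adjusted p = 0.021), were both lost over measured genes alone (adjusted p = 0.13 for each) and had an adjusted p = 0.76 with an estimated correlation. Chaperones and proteases, with 3 of 9 genes higher in every scaling and 4 adjusted over the list alone, were not called. The adjusted p-values of lists not called lay between 0.081 and 0.77.

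The limma fit called 3557 features higher and 849 lower in the mutant at CT17.5. Of these, 196 and 464 held in every scaling, among them 39 and 208 protein genes. Of the 3557 called higher, 1469 were measured in neither genotype and 206 in wild type alone, so those calls rest on mutant spots at background. The split of directions depended on the scaling and was 938 to 1037 with quantile normalization, 1164 to 911 with the series table and 283 to 1189 with the percentile of spots above background on all arrays. Leaving out 1 array moved the count to 2573 and 1444 without wild type replicate 1 or 2 and to 1323 and 1617 without mutant replicate 1 or 2.

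At CT5.5 of day 6 the comparison asked what differs after 6 days of light and dark. Genes for inorganic carbon uptake were far lower in the mutant: sbtA, for a bicarbonate transporter, at -4.88 ± 0.46 (adjusted p = 7.6e-06), its neighbour sbtB at -4.54 ± 0.42, cupA and ndhF3 of the CO2 uptake form of NDH-1 at -4.51 ± 0.23 and -5.27 ± 0.44, and cmpA of the bicarbonate transporter BCT1 at -4.49 ± 0.27, with ndhF3 and cmpA on 1 of 2 mutant arrays. No mutant array measured cmpB, cmpC or cmpD, which were at least 8.98-fold, 5.32-fold and 5.33-fold lower. The flavodiiron genes flv2 and flv4, known to protect photosystem II, fell, flv2 at -4.70 ± 0.31 on 1 mutant array and flv4 at -4.08 ± 0.34. Phosphate uptake genes rose, pstC2 by 2.87 ± 0.23 and pstC1 by 2.54 ± 0.18, and pstS2 was at least 3.1-fold and phoA, for an alkaline phosphatase, at least 2.87-fold higher, the last on 1 mutant array. Of NDH-1, the complex of respiration and cyclic electron flow, ndhI fell by 3.03 ± 0.36, as did ndhB at -2.61 ± 0.28 and ndhJ at -2.32 ± 0.22.

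Other genes that rose at day 6 were petC2, for a Rieske protein, by 3.14 ± 0.21, kaiC3, a further copy of kaiC, by 2.15 ± 0.42, chlL and chlN by 2.02 ± 0.35 and 1.73 ± 0.30, futA1 of iron uptake by 1.55 ± 0.23 and amt1 by 1.28 ± 0.19. These rises and those of phosphate uptake are relative to the level of each array. The 75th percentile of the mutant arrays was 0.200 times that of wild type, and whether the amounts of these transcripts rose was not tested. Lower in every scaling were tal and gnd of sugar breakdown at -1.77 ± 0.21 and -1.75 ± 0.20, por, for light-dependent chlorophyll synthesis, at -1.72 ± 0.25, rpaB, for a response regulator, at -1.47 ± 0.24, clpC at -1.23 ± 0.18 and hspA at -1.12 ± 0.34. The antisense feature slr0304-as1 was higher by 6.95 ± 0.34 (adjusted p = 2.8e-07) and slr0216-int1 by 6.66 ± 0.33. No wild type array measured sll0901-as1, which was at least 74.5-fold higher.

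In inorganic carbon uptake 9 of 12 genes were lower at day 6 and 0 higher in every scaling, 3 did not pass so, while 9 were lower and 1 higher adjusted over the list alone. The median of the 7 genes measured in both genotypes was -4.59 relative to the median protein gene (camera, adjusted p = 2.6e-07; adjusted p = 0.33 with an estimated correlation). NDH-1 core had 14 of 16 genes lower and 2 not passing in every scaling, 15 lower adjusted over the list alone, and a median of -1.85 (adjusted p = 2.6e-07; adjusted p = 0.42 with an estimated correlation). Phosphate uptake had 8 of 11 genes higher and 3 not passing in every scaling, 11 higher adjusted over the list alone, and a median of 2.28 over 8 measured genes (adjusted p = 1.4e-04; adjusted p = 0.33 with an estimated correlation). In glycogen and sugar breakdown 5 of 17 genes fell in every scaling, while 8 were lower and 2 higher adjusted over the list alone. The median of 12 measured genes was -0.76 (adjusted p = 0.0072; adjusted p = 0.45 with an estimated correlation). Terminal oxidases had 1 of 8 lower in every scaling, 6 lower adjusted over the list alone and a median of -0.51 over 2 measured genes (adjusted p = 0.0020; adjusted p = 0.42 with an estimated correlation). Chaperones and proteases had 4 of 9, 6 and -0.71 (adjusted p = 0.016; adjusted p = 0.53 with an estimated correlation). For pili, motility and cAMP the counts were 5 of 17 lower in every scaling, 9 lower and 2 higher adjusted over the list alone, with a median of -0.63 over 15 measured genes (adjusted p = 0.013; adjusted p = 0.42 with an estimated correlation). High light and oxidative stress had 5 of 16 lower in every scaling, 6 lower and 3 higher adjusted over the list alone, and a median of -0.46 over 15 measured genes, while photosystem II had 3 of 26, 2 lower and -0.32 (adjusted p = 0.013 and 0.012; adjusted p = 0.57 with an estimated correlation for both). The bidirectional hydrogenase had 0 of 5 in every scaling, 3 lower adjusted over the list alone and -0.53 for its 1 measured gene (adjusted p = 0.016; adjusted p = 0.42 with an estimated correlation). Over measured genes alone, terminal oxidases and the hydrogenase had too few genes to be tested. Ribosomal proteins were called higher with a median of 0.83 and 20 of 26 higher adjusted over the list alone but 0 in every scaling (adjusted p = 0.016; adjusted p = 0.68 with an estimated correlation), a call lost with the percentile of spots above background on all arrays (adjusted p = 0.15). Lists not called had adjusted p-values between 0.057 and 0.99.

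**Figure D3:**
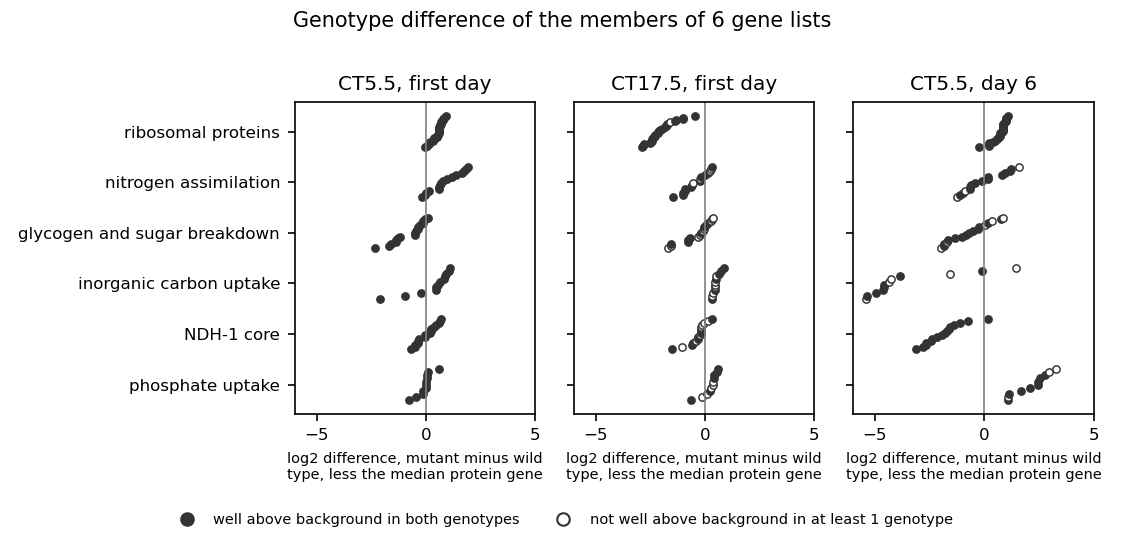
Each point is 1 gene of 6 lists, placed at its log2 difference, mutant minus wild type, less that of the median measured protein gene, at each of the 3 times, with open symbols where at least 1 genotype did not measure it. Most inorganic carbon uptake and NDH-1 genes lie to the left at day 6, 9 of 12 and 14 of 16 being lower in every scaling, with medians of -4.59 and -1.85 over genes measured in both genotypes, and most ribosomal protein genes do at CT17.5, with a median of -2.15.

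The limma fit called 3429 features higher and 1619 lower at day 6. Of these, 1079 and 825 held in every scaling, among them 329 and 347 protein genes and 320 and 40 antisense features. Of the 3429 called higher, 724 were measured in neither genotype and another 724 in wild type alone, so those calls rest on mutant spots at background. The split was 2381 to 2134 with quantile normalization, 2344 to 2096 with the series table and 2042 to 3129 with the percentile of spots above background on all arrays.

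The mean of the 3 genotype differences asked what the mutant changed on average, which does not show that the times were alike. The median measured protein gene had a mean difference of 0.12, and values here are relative to it. The response regulator gene rpaB fell by 1.46 ± 0.14 (adjusted p = 3.8e-05), as did tal, for transaldolase, at -1.49 ± 0.12. By contrast, petC2 rose by 1.18 ± 0.12 and feoB, for ferrous iron uptake, by 1.05 ± 0.16. Among features outside the fixed lists ssr2062 fell by 3.33 ± 0.30, ssr2786 rose by 1.78 ± 0.35 and slr1594-int3 by 2.44 ± 0.16. Both rpaB and tal were lower at each time, rpaB at fitted differences of -1.51, -1.04 and -1.47 at CT17.5, the first CT5.5 and day 6, and tal at -1.08, -1.26 and -1.77. They were 2 of the 3 protein genes called at all 3 times in every scaling, the other being sll0450, among 45 features that included 38 spacer features, all lower.

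NDH-1 core had 5 of 16 genes lower in every scaling in the mean, 13 lower adjusted over the list alone and a median of -0.75 over 9 measured genes (camera, adjusted p = 1.3e-05; adjusted p = 0.49 with an estimated correlation). Inorganic carbon uptake had 5 of 12 lower in every scaling, 9 lower and 1 higher adjusted over the list alone and a median of -1.07 over 6 measured genes, and glycogen and sugar breakdown had 2 of 17, 8 lower and -0.31 over 5 (adjusted p = 1.4e-05 for both; adjusted p = 0.29 with an estimated correlation for both). By time, the median of inorganic carbon uptake was 0.55 at CT17.5 (not called), 0.60 at the first CT5.5 (called higher, but not with an estimated correlation, adjusted p = 0.49, or with quantile normalization, 0.21) and -4.59 at day 6, so only its day 6 median was negative. NDH-1 core was at -0.32, 0.066 and -1.85, phosphate uptake at 0.41, 0.011 and 2.28, and pili, motility and cAMP at -1.28, 0.32 and -0.63 in that order. Over measured genes alone the call of glycogen and sugar breakdown was lost (adjusted p = 0.11). Phosphate uptake had 3 of 11 higher in every scaling, 11 higher adjusted over the list alone and a median of 0.70 over 6 measured genes (adjusted p = 5.0e-04). Pili, motility and cAMP had 6 of 17 lower and 1 higher, 9 lower and 3 higher adjusted over the list alone and -0.50 over 13 measured genes (adjusted p = 0.0025; adjusted p = 0.29 with an estimated correlation for both). In all, 1 list was called higher and 9 lower. The limma fit called 3394 features higher and 1149 lower, and 648 and 367 held in every scaling. The split was 2266 to 1739 with quantile normalization, 2293 to 1686 with the series table and 1221 to 2808 with the percentile of spots above background on all arrays.

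**Figure D4:**
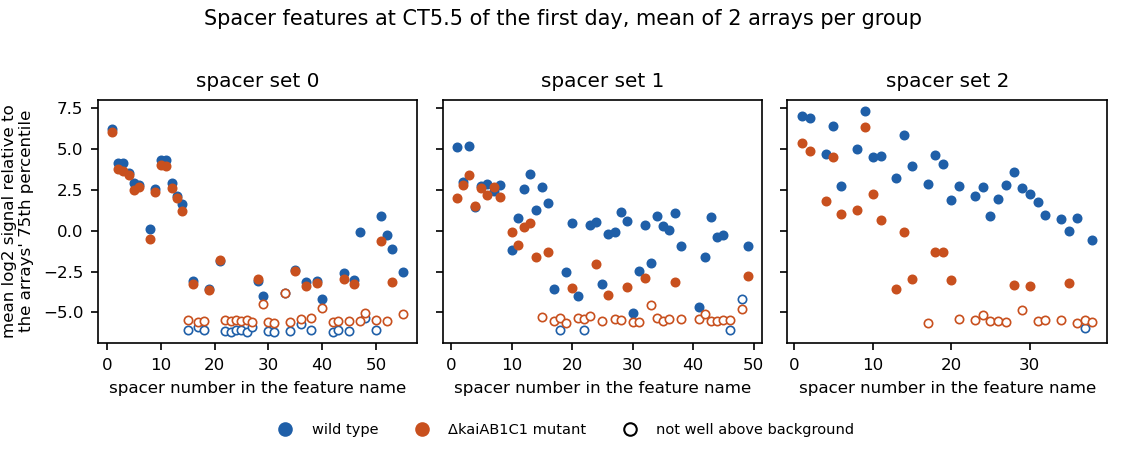
The mean log2 signal of 2 arrays, relative to the array's 75th percentile, is plotted against the spacer number for sets 0, 1 and 2 at the first CT5.5, with wild type in blue, the mutant in orange and open symbols where a feature was not well above background. Among spacers measured in both genotypes, the median difference was -0.24 in set 0, -2.30 in set 1 and -3.81 in set 2. In set 0 it was 0.61 at CT17.5 and 3.03 at day 6, times that are not drawn.

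Differences of the genotype difference between times, from which a slide effect common to both genotypes cancels, were tested with limma, and values are relative to median differences of 0.43 and 0.12 where these arose. From the first CT5.5 to CT17.5, ribosomal proteins had 18 of 26 genes with a lower difference in every scaling, 24 adjusted over the list alone and a median of -2.57 over 25 measured genes (camera, adjusted p = 2.1e-23; adjusted p = 0.29 with an estimated correlation). Nitrogen assimilation had 5 of 16, 9 and -1.45 by the same measures, the last over 12 measured genes (adjusted p = 3.0e-06). It held with an estimated correlation (adjusted p = 0.036). From the first CT5.5 to day 6, inorganic carbon uptake had 6 of 12 lower in every scaling, 9 lower and 1 higher adjusted over the list alone and a median of -5.15 over 7 measured genes (adjusted p = 5.5e-07; adjusted p = 0.22 with an estimated correlation). The difference of flv2 fell by 5.77 ± 0.44 and that of ndhF3 lay at -5.74 ± 0.62. NDH-1 core had 9 of 16 lower in every scaling, 13 lower adjusted over the list alone and a median of -2.01 (adjusted p = 8.5e-07; adjusted p = 0.43 with an estimated correlation). Phosphate uptake had 7 of 11 higher, 11 higher and 2.46 over 8 measured genes (adjusted p = 2.2e-04; adjusted p = 0.22 with an estimated correlation). From CT17.5 to day 6, ribosomal proteins had 19 of 26 higher in every scaling, 25 adjusted over the list alone and a median of 2.58 over 25 measured genes (adjusted p = 1.9e-15; adjusted p = 0.37 with an estimated correlation). Lists called higher and lower numbered 0 and 10, 1 and 7, and 3 and 8 in these 3 contrasts, of which 6 calls are given. The fit called 2868 features higher and 720 lower for CT17.5 against the first CT5.5, 3268 and 1168 for day 6 against the first CT5.5, and 1596 and 1359 for day 6 against CT17.5, of which 164 and 315, 957 and 618, and 566 and 316 held in every scaling. With quantile normalization the splits were 418 to 756, 1836 to 1505 and 1228 to 1169. They were, with the deposited log2 values, 543 to 689, 1750 to 1459 and 1045 to 1028, and with normexp 1468 to 640 in the first and 2740 to 830 in the last of them. For CT17.5 against the first CT5.5, each array's median gave 1585 to 785. With the percentile of spots above background on all arrays the splits were 854 to 765, 2270 to 1986 and 1070 to 1637.

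In wild type, the change from CT5.5 to CT17.5 of the first period asked how transcripts of the unaltered clock strain differed between these times. Photosynthesis genes fell: psaC of photosystem I at -3.70 ± 0.20, psbO of photosystem II at -3.12 ± 0.19, cpcB of the phycobilisome at -3.16 ± 0.22, atpD of ATP synthase at -3.46 ± 0.26 and prk, for phosphoribulokinase, at -4.03 ± 0.24. Carbon uptake genes fell with them, sbtA at -6.69 ± 0.46 (adjusted p = 6.0e-07) and flv2 at -6.61 ± 0.31, the latter measured on 1 array at CT17.5. In NDH-1, ndhG fell by 5.19 ± 0.21. The small heat shock gene hspA rose by 7.19 ± 0.34, feoB by 4.09 ± 0.28, nblA1, for phycobilisome breakdown, by 3.33 ± 0.18 and the sigma factor gene sigH by 3.26 ± 0.19. Rises and falls with time are relative to the level of each array. The geometric mean of the 75th percentile was 695 at CT17.5 beside 2797 at CT5.5 in wild type, and whether transcript amounts changed was not tested. In every scaling and adjusted over the list alone, respectively, 19 and 21 of 26 photosystem II genes were lower, 10 and 10 of 12 photosystem I genes, 11 and 13 of 13 phycobilisome genes, 9 and 9 of 9 ATP synthase genes, 14 and 15 of 16 NDH-1 genes and 10 and 11 of 12 inorganic carbon uptake genes. The other NDH-1 gene to pass, 1 of the 16, was higher. Their medians over 25, 12, 12, 9, 14 and 8 measured genes were -1.48, -2.56, -2.10, -3.14, -3.61 and -4.96 (camera, adjusted p between 2.7e-05 and 3.1e-05; adjusted p = 0.32 with an estimated correlation for all 6). They were 6 of the 13 lists called lower. The 2 called higher were the phototaxis operon, with 2 of 6 genes higher in every scaling, 4 adjusted over the list alone and a median of 1.12 (adjusted p = 0.016; adjusted p = 0.32 with an estimated correlation), and chaperones and proteases, with 3 of 9 higher and 1 lower, 6 higher and 1 lower, and 1.18 (adjusted p = 0.038; adjusted p = 0.35 with an estimated correlation). Chaperones lost the call over measured genes alone (adjusted p = 0.062), with quantile normalization (0.13) and with the series table (0.13). The limma fit called 2591 features higher and 2762 lower, and 1252 and 1226 held in every scaling. Of the 2591 called higher, 6 were measured at neither time and 325 at CT5.5 alone. Splits were 4127 to 1759 with normexp, 3697 to 1703 with each array's median and 1455 to 4207 with the percentile of spots above background on all arrays.

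For the same change in the mutant, values are relative to a median of 0.41. They are also relative to the level of each array, whose 75th percentile had a geometric mean of 464 at CT17.5 beside 2627 at CT5.5. There hspA rose by 9.50 ± 0.34, feoB by 3.44 ± 0.28, sigH by 3.14 ± 0.19 and dnaK2 by 3.13 ± 0.25. By contrast, sbtA fell by 6.70 ± 0.46, as did ndhJ at -5.20 ± 0.22, prk at -4.87 ± 0.24, atpA at -4.32 ± 0.23, psbB at -4.17 ± 0.20 and psaC at -4.00 ± 0.20. The ribosomal protein genes rplV and rpsI fell, at -3.43 ± 0.23 and -3.34 ± 0.21. In all, 26 of 26 genes of that list were lower in every scaling and adjusted over the list alone, with a median of -2.81 over 25 measured genes (camera, adjusted p = 2.9e-11; adjusted p = 0.26 with an estimated correlation). It was 1 of 15 lists called lower, and 1 was called higher. The fit called 3932 features higher and 2118 lower. Of these, 1570 and 985 held in every scaling. Of the 3932 called higher, 131 were measured at neither time and 1244 at CT5.5 alone, so those calls rest on spots at background. Splits were 4828 to 1635 with normexp and 2261 to 3534 with the percentile of spots above background on all arrays.

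Between CT5.5 of the first period and of day 6, wild type differed less, with a median of -0.11 to which its values are relative. The heat shock genes hspA and clpB1 rose by 3.44 ± 0.34 and 2.12 ± 0.19, ocp by 1.96 ± 0.24, por by 1.62 ± 0.25, apcE of the phycobilisome core by 1.52 ± 0.25 and slr0798 by 5.21 ± 0.32. By contrast, futA2 of iron uptake fell by 1.92 ± 0.29, as did gap1 at -1.27 ± 0.23 and sigE at -1.13 ± 0.27. Phycobilisome had 1 of 13 genes higher in every scaling, 12 higher adjusted over the list alone and a median of 1.04 (camera, adjusted p = 1.1e-08). Chaperones and proteases had 4 of 9, 8 and 0.94 (adjusted p = 1.9e-06; adjusted p = 0.42 with an estimated correlation for both). They were 2 of 8 lists called higher, and 1 was called lower. The fit called 398 features higher and 1112 lower, and 133 and 193 held in every scaling. Splits were 299 to 386 with quantile normalization, 355 to 401 with the series table, 713 to 562 with each array's median, 574 to 546 with normexp and 174 to 2054 with the percentile of spots above background on all arrays. Without replicate 2 of day 6, 465 features were called.

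In the mutant the same interval had a median of 0.13. Relative to it flv2 fell by 6.25 ± 0.31 on 1 array of day 6, as did flv4 at -5.37 ± 0.34, sbtA at -4.77 ± 0.46, cupA at -4.40 ± 0.23, ndhJ at -2.67 ± 0.22 and nrtB at -2.02 ± 0.20. By contrast, chlN rose by 2.78 ± 0.30, pstC2 by 2.56 ± 0.23, pstC1 by 2.47 ± 0.18 and kaiC3 by 2.26 ± 0.42. These rises are relative to the level of each array, whose 75th percentile had a geometric mean of 602 at day 6 beside 2627 at the first CT5.5. Inorganic carbon uptake had 9 of 12 genes lower in every scaling, 9 lower and 1 higher adjusted over the list alone and a median of -4.49 over 7 measured genes (camera, adjusted p = 2.2e-06; adjusted p = 0.21 with an estimated correlation). NDH-1 core had 13 of 16 lower, 15 lower and -1.84 by the same measures (adjusted p = 8.6e-07; adjusted p = 0.44 with an estimated correlation). Phosphate uptake had 8 of 11 higher, 11 higher and 2.18 over 10 measured genes (adjusted p = 2.9e-04; adjusted p = 0.21 with an estimated correlation). In this contrast 2 lists were called higher and 7 lower. The fit called 3267 features higher and 1700 lower. Of these, 968 and 776 held in every scaling. Of the 3267 called higher, 137 were measured at neither time and 1170 at the first CT5.5 alone, so those calls rest on spots at background. The split was 2332 to 2212 with quantile normalization, 2298 to 2231 with the series table, 4391 to 1390 with normexp and 1688 to 3364 with the percentile of spots above background on all arrays.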

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

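Tests of the antisense and spacer features were chosen only after the result was seen. A ratio chosen before, of antisense spots to negative controls, decided nothing about genomic DNA. Mutant over wild type, it was below 1 not only at day 6 (0.885) but at the first CT5.5 (0.940) and CT17.5 (0.955). Whether dim mutant arrays or another cause lowered it was not tested. Results are listed because the genotype difference itself differed between times by limma's test of that difference, which called 3588 features for CT17.5 against the first CT5.5, 4436 for day 6 against the first CT5.5 and 2955 for day 6 against CT17.5. For CT17.5 against the first CT5.5 the fitted log2 values, given here and below without taking off the median difference, were 5.20 for ssr2062-5'UTR, -4.33 for slr1152-int1 and -4.26 for Spacer3-1-x, and, for features not measured in every group, whose values rest in part on spots at background and give no size here or below, 5.28 for NC-334, 5.20 for NC-27, 5.00 for sigE (sll1689), 4.53 for slr0758-int1, -7.09 for Spacer4-1-x, -4.36 for ssl2250-5'UTR and -4.06 for Spacer10-1-x. For day 6 against the first CT5.5 they were 7.53 for slr0304-as1, 7.13 for slr0216-int1, 6.90 for slr0216-int2, -5.65 for flv2 (sll0219) and -5.62 for ndhF3 (sll1732), and, not measured in every group, 8.28 for sll0901-as1, 7.39 for kaiA-as1-0-x, -6.19 for cmpB (slr0041), -5.72 for slr0040-int1 and -5.59 for sll0217-int1. For day 6 against CT17.5 they were 6.98 for slr0304-as1, 6.80 for ssl1045-5'UTR, 6.18 for slr0216-int1 and -6.23 for ndhF3, and, not measured in every group, 6.37 for slr1511-as2, 6.31 for sll0901-as1, -6.37 for sll0217-int1, -6.28 for cmpB, -6.15 for slr0040-int1 and -6.12 for sll0217-int2. In control spots outside the comparisons, the bright corner spots of the mutant arrays were 4.30 times those of wild type at day 6, beside 0.955 at CT17.5 and 0.870 at the first CT5.5.

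At day 6 more antisense features were higher in the mutant than lower, 320 against 40 in every scaling. A noise floor raised by the scaling of dim arrays would lift protein genes of equal wild type level alike, and genomic DNA in the mutant RNA would too, since DNA holds both strands of every locus. Both are argued against as the whole source for the 748 brighter antisense features measured on both wild type arrays, of which 226 were higher, 6.17 times the 36.6 that such protein genes would give, but both stay open for the 187 dimmest, of which 64 were higher, 1.28 times the 49.8 of protein genes. A biological difference and array position, which went with genotype on every slide, stay open and were not tested. Of the 320 features, 162 were among the 336 that rose in wild type from CT5.5 to CT17.5, where independent sets would share 73.6 of 1460, but the mutant arrays of day 6 and the wild type arrays of CT17.5 were both dim, so an effect of dimness on this overlap was not excluded.

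Of the 45 spacer features of set 1, 35, 25 and 14 were lower in the mutant in every scaling at CT17.5, the first CT5.5 and day 6, as were 28, 30 and 31 of the 32 of set 2, and 0 were higher, although among spacers measured in both genotypes Spacer10-1-x, Spacer7-1-x and Spacer4-1-x had differences of 1.10, 0.25 and 0.068 at the first CT5.5 and Spacer2-1-x of 0.99 at day 6. Of the 49 in set 0, 5, 3 and 1 were lower and 1, 0 and 14 higher, with medians of 0.61, -0.24 and 3.03 over those measured in both genotypes, while 6 of 30 measured in wild type at the first CT5.5, Spacer47-0-x and Spacer52-0-x among them, were on no mutant array. Lower detection on the mutant arrays is argued against as the whole source at the first CT5.5, since 33 of the 72 spacers of sets 1 and 2 measured in wild type were on no mutant array, where protein genes of equal wild type level would give 0.165. The protein genes were matched by level in 4 bins and not by number of probes. Any 1 probe above background counts a gene as measured, so 0.165 may be too low. In the 2 middle bins 10 of 18 and 9 of 18 spacers were lost, beside 0 of 425 and 0 of 140 protein genes. Spacers numbered above 14 could be missing from the DNA of the mutant strain, a variant apart from the deletion. Of 48 measured in wild type, 32 were measured on no mutant array at any time but 16 were measured on at least 1, so a loss of those 32 stays open. The source of the signal of the 16 was not tested, so a loss of all 48 was not excluded. Lower transcription in the mutant stays open beside a loss, and no DNA was analysed here that would separate them.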

How the results depend on the processing

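The tests with the percentile of spots above background on all arrays, the counts of measured or bounded calls, the list tests on measured genes and the crossed block were chosen only after the result was seen. Depth, the signal over background, limits these results most where mutant arrays were dim, at CT17.5 and day 6, and the counts called higher and lower there moved with the scaling. Of the values of named genes under alternatives, arrays left out included, 16900 kept direction and side of the threshold, 1038 lost the call, 15 gained it and 38 reversed. Much of this agreement follows from construction. An array left out of another group, another threshold or prior, or another set of features tested does not change a fold change. Genes outside the deleted cluster were named because they were called, so they could hardly gain a call. The filter for all 12 arrays scored only 330 values. The tally is therefore no measure of robustness. Where a value or count moved, the cause was not tested unless the construction of the setting shows it.

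Counts of called features moved by over 1.5 times as follows. At CT17.5 there were 1975 with quantile normalization, 2075 with the series table, 1472 with the percentile of spots above background on all arrays, 1230 with a 2-fold threshold and 2507 when measured or bounded calls were counted. At the first CT5.5 there were 227 with array weights and 132 with the arrays of that time alone, where fewer samples give the spread. Counting measured or bounded calls gave 3148 at day 6 and 2197 in the mean, for which a 2-fold threshold gave 840. For the difference between CT17.5 and the first CT5.5 the counts were 2108 with normexp, 1174 with quantile normalization, 2370 with each array's median, 1619 with the percentile of spots above background on all arrays, 1232 with the series table and 1812 measured or bounded. Measured or bounded calls were 2483 for day 6 against the first CT5.5, 1486 for day 6 against CT17.5, 3941 for the mutant's change to CT17.5 and 3146 for its change to day 6. For wild type from the first CT5.5 to day 6 the counts were 685 with quantile normalization, 756 with the series table, 833 with a 2-fold threshold, 489 with array weights and 735 with the arrays of those times alone. Fewer features were tested when only those above background on all 12 arrays were kept, which gave 1710 at CT17.5, 109 at the first CT5.5, 1921 at day 6, 1859 in the mean, 1327, 1722 and 1355 for the differences between times, 2226 and 532 for the changes of wild type to CT17.5 and day 6, and 2397 and 1942 for those of the mutant. With protein genes alone the counts were in the same order 1891, 176, 2002, 1785, 1601, 1812, 1096, 2204, 600, 2446 and 2020.

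Leaving out each array in turn, with the lone array of a group assumed to vary like the other groups, gave 1323 to 4895 calls at CT17.5, 217 to 608 at the first CT5.5, 4212 to 5293 at day 6 and 3967 to 4672 in the mean. For the differences between times it gave 1632 to 3889, 3770 to 4506 and 1942 to 3301, for wild type 4544 to 5490 at CT17.5 and 465 to 1687 at day 6, and for the mutant 5401 to 6223 and 3985 to 5229. Single arrays moved the difference between CT17.5 and the first CT5.5, to 2356 and 1733 without wild type replicate 1 or 2 of CT17.5, 1632 and 1836 without the mutant ones, and 2282 and 2080 without mutant replicate 1 or 2 of CT5.5. Without mutant replicate 1 of CT17.5 the difference between day 6 and CT17.5 had 1942.

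Lists called with an estimated correlation numbered 1 at the first CT5.5 and 1 for the difference between CT17.5 and the first CT5.5, and 0 in each of the other 9 contrasts, where 6 to 16 had been called. With fry, which asks whether the genes of a list move one way and does not compare them with other genes, 6 lists were called at the first CT5.5 instead of 13 and 14 for the mutant's change to day 6 instead of 9. Over measured genes alone 4 lists were called in the mean instead of 10.

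The replicate numbers did not pair the samples: across features the deviations of arrays with the same number correlated at -0.08, 0.22 and -0.11 at CT17.5, the first CT5.5 and day 6. With a block for the number there were 4233, 351 and 4897 calls at these times, 4356 in the mean, 3147, 4269 and 2697 for the differences between times, 5185 and 1113 for wild type and 5989 and 4834 for the mutant. The block called 6, 13, 11, 11, 10, 8, 11, 15, 9, 17 and 9 lists in that order. A crossed pairing at day 6 gave 5120 calls.

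For the deleted genes, with normexp the log2 differences at day 6 were 0.64 for kaiA, which reversed, 0.34 for kaiB1 and 0.43 for kaiC1, and at CT17.5 0.37 for kaiA, 0.35 for kaiB1 and 0.42 for kaiC1 (adjusted p = 0.051), all of dim spots. With quantile normalization they were -0.79 for kaiA at day 6, 0.45 for kaiC1 at CT17.5, and -0.63 for kaiC1 and -0.52 for kaiB1 at the first CT5.5, and with the series table slr0757, which is kaiB1, was at -0.17 at day 6. With normexp slr0756, which is kaiA, had 0.64 at day 6 and 0.28 in the mean, and with quantile normalization -0.00186 in the mutant's change to day 6.

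Named genes that reversed in the genotype difference at day 6 were sll1578 at -0.27 with normexp, -0.43 with quantile normalization, -0.17 with the percentile of spots above background on all arrays and -0.54 with the series table, sll0486 at -0.23 with quantile normalization and -0.086 with the series table, and sll1638 at -0.12 and slr1838 at -0.11 with the percentile. At CT17.5 the series table gave -0.00203 for sll1327, -0.012 for slr1857, -0.00787 for slr2083, -0.015 for sll1453 and -0.017 for slr0506. In the mean the percentile gave -0.043 for sll1032. In the change of wild type to CT17.5 normexp gave 0.25 for sll0486 and 0.12 for sll0288, and the series table -0.00308 for sll0654. In the mutant's change to CT17.5 the percentile gave -0.074 for slr0115, -0.091 for sll0041 and -0.28 for sll1226, for which the median over probes gave -0.17. In the mutant's change to day 6 normexp gave 0.055 for sll0247, 0.025 for sll1224, -0.033 for sll1577 and -0.026 for sll1579. Quantile normalization there gave -0.072 for sll1578, -0.17 for sll1577 and -0.017 for sll1579. The percentile gave -0.089 for ssr0390, -0.057 for sll1577 and -0.039 for sll1579, and the series table -0.33 for sll1578, -0.33 for sll1577 and -0.087 for sll1579.

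The count of the mean genotype difference was set against other splits of the arrays within times. Of 100 splits drawn from 108, the real one included, 2 called as many features. Most other splits put arrays of both genotypes in the same group, which widens their spread and lowers their counts by construction. The test therefore cannot exclude chance for the mean difference and cannot separate genotype from array position. The real split called 4543 and the highest other 5208, and that split differs from the real one by reversing the genotypes at the first CT5.5.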

Other observations

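The test of dark-likeness was chosen only after the result was seen, and that of compression was chosen before. In protein genes called in every scaling, the genotype differences at different times were compared: CT17.5 with 247 and the first CT5.5 with 61 shared 5 in the same and 4 in opposite directions, CT17.5 and day 6 with 676 shared 97 and 12, and the first CT5.5 and day 6 shared 17 and 2. Besides the genes already described, the mutant's change from CT5.5 to CT17.5 raised isiA by 2.73 ± 0.28 and pstB2 of phosphate uptake by 2.53 ± 0.21 relative to the median protein gene, and its change to day 6 lowered pilM and pilO, for assembly of type IV pili, to -2.08 ± 0.21 and -2.08 ± 0.18. Wild type raised sigB by 1.46 ± 0.18 from the first CT5.5 to day 6.

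One hypothesis is that the mutant at CT5.5 of day 6 may share changes with wild type going from CT5.5 to CT17.5. Over 1240 protein genes above background on all 12 arrays, the genotype difference at day 6 correlated with that change of wild type at r = 0.346 and rho = 0.299 with the 75th percentile scaling, the lowest of the scalings, and at r = 0.490 with normexp, across genes, which are not independent replicates. The 2 comparisons share no arrays. Of 3265 protein genes, 160 were lower and 114 were higher in both in every scaling, where independent sets would share 59.1 and 35.3, while 1 was higher at day 6 and lower at CT17.5 beside 56.0 for independent sets and 39 were lower at day 6 and higher at CT17.5 beside 37.2. Compression of dim features on dim arrays stays open, since over the 620 brighter genes r was 0.155 and rho 0.014 with the 75th percentile scaling, the lowest, and 0.350 and 0.284 with normexp, the highest. Because the mutant arrays of day 6 and the wild type arrays of CT17.5 were both dim, the shared change and the compression cannot be told apart.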
